A study of Mus musculus with 6 samples.

How the data were processed

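Kidney RNA from mice after ischaemia-reperfusion injury was sequenced in 6 libraries, 3 labelled wild type and 3 labelled Cxcr2 knockout. Samples were grouped by the genotype and title in the labels, and the replicate numbers were taken from the titles. The deposited values are a signal per gene, namely read counts divided by 1 size factor per library, as the values themselves show. In each library 100% of the deposited values were whole multiples of a single step within 0.001 reads, so whole reads could be recovered, 15518083 to 20356601 per library. The median ratio of a library to the geometric mean over genes was 1.004 in all 6, which is the form that median-of-ratios size factors give, and the factors ran from 0.879 to 1.20. Per the submitters' processing notes the genome build was mm10. The aligner, the counting program, the use of strand, the annotation release and the library kit are not given in the sources used here. Of the 25805 gene identifiers, 99.9% were in GENCODE M21 and 97.1% had the same start and end there. Gene symbols and coordinates are those of the deposited files, and 4 genes of the lists were matched by an older symbol. Genes that share sequence with a near-identical copy have uncertain counts, since the treatment of reads with several matches is not known.

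The design fixed beforehand assumed raw counts and edgeR, with limma for files that hold only FPKM or TPM values. It named no test for normalized counts such as those deposited. The limma test was taken over for them as the main test once the form of the values was known. It was limma 3.58.1 (trend and robust options) on log2(normalized count + 1). Genes with a mean normalized count of at least 1 were kept, 21721 in all. Fold changes are on this scale, which understates the change of low genes. Adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05. The quasi-likelihood test of edgeR 4.0.16 (TMM factors, its own filter, 15915 genes) and the Wald test of DESeq2 1.42.0 (16222 genes with an adjusted p) were run on the recovered reads as alternatives, in R 4.3.3. With 3 libraries in each group an exact permutation test of a single gene cannot go below 0.1, so single genes were tested with the models fitted across all genes.

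The 33 gene lists were fixed in advance: proximal tubule, thick limb and distal tubule, collecting duct, podocyte, endothelial, neutrophil, macrophage and monocyte, T and NK cell, and B and plasma cell markers, and fibroblast and matrix, tubular injury, erythrocyte, CXCR2 ligand, autophagy, lysosome, NF-kB, ERK component, ERK response, acute phase and complement, interferon-stimulated, antigen presentation, cell cycle, pyroptosis and necroptosis, apoptosis, ferroptosis, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, glycolysis and hypoxia, heat shock, unfolded protein response, NRF2 target and sex-linked genes. Each list was tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over the 33 lists. The values of Aldoa are listed under 2 identifiers, and both entered the glycolysis list. The KEGG and GSEA collections that the series text names were not used here. An added list of 20 fat cell markers was written after the values had been seen.

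The genes taken for the text were Cxcr2, Atg5, Rela, Mapk3, Map1lc3b, Sqstm1, Becn1, Havcr1 and Lcn2 whatever their values, then genes with an official symbol, no overlap between groups and a group mean of at least 1 CPM. Of these, up to 12 per direction past the threshold were to be taken, filled up to 8 by smallest p where fewer passed. From each list up to 4 members with the smallest p were named, here 4 for lists called by camera and 2 for the others. Some genes that this rule takes are not reported here. Other genes are stated to have been chosen after their values were seen.

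Before the real data were modelled, the tests were tried on simulated counts with the means and depths of these libraries. Their dispersion followed the trend with mean level. The 200 changed genes, 50 at each size, were all drawn from genes with a mean normalized count of at least 50. In the comparison of knockout with wild type over 21534 genes, limma recovered 26% of 2-fold, 90% of 4-fold and 100% of 8-fold and 16-fold changes, with 8 false calls, and DESeq2 made 31 false calls. The simulated genes had no spread of their own around that trend, so these shares do not give the recovery in the real data. There Stra6 (log2 fold change 4.02) and Klk1b9 (-4.10) did not pass limma's threshold (limma adjusted p = 0.155 and 0.181). A gene not called may therefore still differ by a large factor. The median SE of a log2 fold change in the real data was 0.39 over all tested genes and 0.23 at a mean of at least 50. All pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom 34.0 to 179), so no library was counted as a repeat of another.

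The alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 10, TMM scaling, the replicate number as a block, DESeq2, edgeR with TMM or RLE factors, the list tests above, leaving out each library in turn, and the 10 splits of the 6 libraries into 3 and 3. Near-identical copies were searched with blastn 2.17.0 in the GENCODE M21 transcripts at 95% identity over at least 100 nucleotides. Figures were drawn with matplotlib 3.10.9.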

Results

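RNA sequencing measured gene expression in the kidneys of mice after ischaemia-reperfusion injury, in which blood flow to the kidney is stopped and restored, a standard model of acute kidney injury. The 6 libraries form 2 groups of 3, wild type and knockout of Cxcr2, the receptor on neutrophils and other cells for chemokines such as Cxcl1 and Cxcl2. Both groups were injured, and no uninjured kidney was analysed here. The wild-type libraries held 20356601, 17857684 and 15518083 recovered reads and the libraries labelled knockout 17372645, 17467391 and 17937195, over 25805 listed genes. The labels do not say that each library came from a separate animal, so the p-values measure the spread between these samples, which may be technical.

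Cxcr2 itself was not lower in the libraries labelled knockout. Its normalized counts were 15.9, 88.8 and 56.9 in wild-type libraries 1 to 3 and 98.0, 36.8 and 56.6 in labelled-knockout libraries 1 to 3. The means were 53.9 ± 36.6 and 63.8 ± 31.2 (SD, n = 3 each), from 19 to 96 reads per library. The log2 fold change of labelled knockout against wild type was 0.43 (SE 0.64, 95% interval -1.04 to 1.90, limma adjusted p = 0.841) and 0.24 with DESeq2. It ran from -0.27 without wild-type library 1 to 0.94 without wild-type library 2, with 0.070 without labelled-knockout library 1 and 0.77 without library 2. Cxcr2 (ENSMUSG00000026180) lies on chromosome 1 from 74153989 to 74161246 in mm10. The values are sums over the whole gene, and the labels do not say which part of it was deleted, so reads outside a deleted part check nothing. Every direction below is therefore one between the libraries labelled knockout and those labelled wild type.

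The libraries labelled knockout were unlike one another. Over 12841 genes with a mean of at least 50, the first principal component held 48.3% of the variance and set labelled-knockout library 1 (86.0) apart from the other 5 (-27.3 to -4.16). The second held 27.3% and had labelled-knockout library 3 at its end (-57.3). Labelled-knockout libraries 1 and 2 stood at 3.20 and -12.8 on it, below the wild-type libraries (12.2 to 33.6). Against the mean of the other 5 libraries, library 1 had higher neutrophil markers (median log2 difference 2.82, 23 of 23 higher), erythrocyte genes (3.12, 8 of 8) and acute phase and complement genes (1.49, 18 of 18). It also held transcripts of fat cells, such as Ucp1, the uncoupling protein of brown fat, at 7234 normalized counts against 48.4 or less elsewhere. Library 3 had higher interferon-stimulated genes (median 2.90, a 7.49-fold difference, 20 of 21 higher) and antigen presentation genes (1.52, 15 of 15). Ucp1, like the other fat cell genes named here, was chosen after its values were seen.

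The comparison of the groups asks which kidney genes differ with Cxcr2 genotype after injury. Gm8730, a processed pseudogene of the ribosomal protein gene Rplp0, rose in the libraries labelled knockout, from 101 ± 7.94 to 1450 ± 263 normalized counts (SD, n = 3), a log2 fold change of 3.81 (SE 0.20, limma adjusted p = 0.000521). It lies on chromosome 8 from 102864845 to 102865798 and shares nearly all of its sequence with Rplp0, so its count is uncertain. Rplp0 stood at 24608 ± 158 and 19450 ± 3140 normalized counts. Gm8730 was the only gene of 21721 past the threshold with limma and was named after its values were seen. No gene was past it in the lower direction, although 2189 genes had an unadjusted p under 0.05, 855 higher and 1334 lower. Groups did not overlap for 17.7% of genes, where chance gives 10%. The edgeR test on recovered reads also called 1 gene, with 1855 at an unadjusted p under 0.05, and DESeq2 called 316, 105 higher and 211 lower. With limma the count was 4 (3 higher, 1 lower) after TMM scaling and 5 without the filter on low values. It was 6 without labelled-knockout library 1 and 3 without library 3.

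The 16 genes taken by smallest p, 8 in each direction, had no overlap between groups, and none passed limma's threshold (adjusted p 0.0534 to 0.329), while all 16 passed that of DESeq2 (adjusted p of 0.00431 or less). Among the 8 with higher values were Stra6, a cell-surface receptor for retinol-binding protein (log2 fold change 4.02, SE 0.54), and Ptgds, a prostaglandin D synthase (2.15, SE 0.35). The growth factor Mdk (1.69), the endosomal protein Wdfy1 (1.34), the complement genes Cfi (2.20) and C2 (1.41) and the NF-kB cofactor Bcl3 (1.08) had higher values too. Among the 8 with lower values, Id1, an inhibitor of helix-loop-helix transcription factors and a target of BMP signalling, stood at 1384 ± 102 and 485 ± 82.7, a log2 fold change of -1.52 (SE 0.18, limma adjusted p = 0.069). The mitochondrially encoded complex I subunit mt-Nd3 had a log2 fold change of -1.98 (SE 0.20, limma adjusted p = 0.0534). The nuclear pseudogene Gm28438, which is nearly identical to mt-Nd3 and was chosen after its values were seen, had one of 2.79 (SE 0.30, limma adjusted p = 0.0534), so both counts are uncertain. The kallikrein Klk1b9 (-4.10), Popdc3 (-4.75), the retinaldehyde dehydrogenase Aldh1a1 (-1.19), the epithelial proteoglycan Sdc1 (-1.49), cyclin Ccnb1 (-2.35) and the muscle filament Des (-1.76) made up the rest. Ccnb1 (99.2% identity over 1287 bases), Sdc1 (95.2% over 418) and Wdfy1 (96.8% over 125) each share a stretch with another gene, so their counts are uncertain too.

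**Figure D1:**
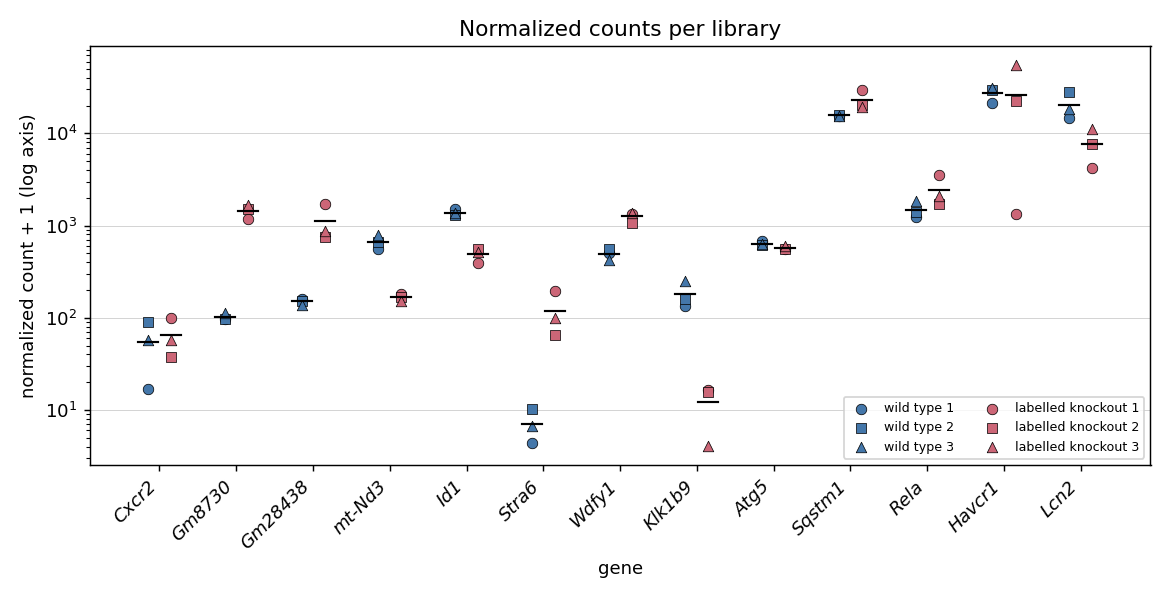
Normalized counts plus 1 (log axis) of 13 genes in each of the 6 libraries, blue for wild type and red for labelled knockout, with symbols for replicate numbers and black bars for group means. Cxcr2 overlaps between the groups, while Gm8730 lies at 96.1 to 110 in wild type and 1164 to 1681 in labelled knockout.

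The study's title names autophagy, ERK signalling, NF-kB p65 and ATG5. Genes of the autophagy machinery were slightly higher in the libraries labelled knockout as a list, with a median log2 fold change of 0.14 and 35 of 47 members higher (camera adjusted p = 0.00972, adjusted p = 0.751 with an estimated correlation). None of the 47 passed limma's test over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05, 4 higher and 1 lower, and DESeq2 called 0. Sqstm1, the cargo receptor p62 that autophagy degrades, stood at 15701 ± 230 in wild type and 23139 ± 5800 in labelled knockout (log2 fold change 0.53, SE 0.20, limma adjusted p = 0.452), and its log2 fold change was 0.33 without labelled-knockout library 1. Atg5, which helps to attach LC3 to membranes, stood at 638 ± 34.1 and 574 ± 26.7 (-0.15, SE 0.15, 95% interval -0.50 to 0.20, limma adjusted p = 0.751). Map1lc3b (0.27, with 0.15 without labelled-knockout library 1 and 0.42 without library 2), Atg2a (0.55), Wdr45 (0.53), Becn1 (-0.18) and Atg4a (-0.49) did not pass either. The list was higher by 0.42 over the wild-type mean in labelled-knockout library 1 and by 0.029 and 0.12 in libraries 2 and 3. Its call was lost without labelled-knockout library 1 (median 0.067, adjusted p = 0.263) and without wild-type library 1 (0.17, adjusted p = 0.0508), and the median was 0.23 without wild-type library 3 and 0.22 without labelled-knockout library 2.

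No ERK list was called over all 6 libraries, while the ERK response genes were called lower without labelled-knockout library 1 (median -0.38, camera adjusted p = 0.000241). Mapk3 (ERK1) stood at 2151 ± 377 in wild type and 2229 ± 344 normalized counts in labelled knockout (SD, n = 3), a log2 fold change of 0.053 (SE 0.19, limma adjusted p = 0.944) that ran from -0.045 to 0.19 with 1 library left out. The 10 ERK components had a median log2 fold change of 0.035 (camera adjusted p = 0.492), at 0.064, 0.10 and 0.16 relative to the wild-type mean in labelled-knockout libraries 1 to 3 and -0.063, 0.018 and 0.048 in wild type, and the 18 ERK response genes one of -0.061 (camera adjusted p = 0.633), with Braf at 0.23 (0.15 without labelled-knockout library 1) and Spred3 at -0.71 among the members of smallest p. NF-kB pathway and target genes were higher as a list, with a median of 0.22 and 19 of 29 higher (camera adjusted p = 0.0248, adjusted p = 0.751 with an estimated correlation). Bcl3 rose, adjusted over the list alone, and no member passed limma over all genes, while 7 had an unadjusted p under 0.05, 6 higher and 1 lower, and DESeq2 called 1. Rela, which encodes p65, stood at 1487 ± 320 and 2439 ± 954 (0.67, SE 0.28, limma adjusted p = 0.477), with 3516 in labelled-knockout library 1 and a log2 fold change of 0.37 without it. Nfkbiz (0.73) and Ccl5 (1.60, and 0.98 without wild-type library 3) had the next smallest p. The NF-kB call was lost without labelled-knockout library 1 (median 0.14, adjusted p = 0.47), labelled-knockout library 3 (0.27, adjusted p = 0.078) or wild-type library 1 (0.23, adjusted p = 0.121), and the median was 0.47 without labelled-knockout library 2. The list stood at 0.65, -0.11 and 0.42 relative to the wild-type mean in labelled-knockout libraries 1 to 3. These values are transcript levels and do not measure phosphorylation, nuclear p65 or autophagic flux.

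Lcn2, the secreted injury marker NGAL, was lower in each library labelled knockout, at 4180, 7747 and 11101 normalized counts against 14679, 27779 and 18445 in wild type. Its log2 fold change was -1.46 (SE 0.38, limma adjusted p = 0.383), and it passed only with DESeq2 (adjusted p = 0.0208). Havcr1, which encodes the tubular injury marker KIM-1, stood at 27170 ± 5005 and 26166 ± 26787, with 1321 in labelled-knockout library 1 and 54545 in library 3. Its log2 fold change was -1.19 (SE 1.30, limma adjusted p = 0.779), 0.39 without library 1 and -2.29 without library 3, and -0.054 with DESeq2 (adjusted p = 0.992). The 25 tubular injury genes had a median of -0.37 with 17 lower (camera adjusted p = 0.0428, adjusted p = 0.751 with an estimated correlation), 2 at an unadjusted p under 0.05, no member past limma over all genes or adjusted over the list alone, and 2 past DESeq2. S100a6 (-2.06), Plaur (-0.37) and Clu (-0.89) followed Lcn2 by p, with S100a6 at -1.23 and Clu at -0.35 without labelled-knockout library 1. Relative to the wild-type mean, the list stood at -0.45, -0.28 and -0.079 in labelled-knockout libraries 1 to 3 and -0.20, 0.12 and 0.076 in wild type. The call was lost without wild-type library 2 (median -0.15, adjusted p = 0.0642), wild-type library 3 (-0.16, adjusted p = 0.123), labelled-knockout library 1 (-0.22, adjusted p = 0.0648) or labelled-knockout library 2 (-0.23, adjusted p = 0.271). It was also lost with a pseudocount of 0.1 (adjusted p = 0.0552) and with a minimum mean of 10 (adjusted p = 0.0608).

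Markers of the proximal tubule, the segment most exposed to ischaemia, were higher as a list (median 0.58, 19 of 25 higher, camera adjusted p = 0.00317, adjusted p = 0.751 with an estimated correlation). The transporters Slc3a1 (0.81), Slc5a2 (1.01) and Slc22a8 (1.02) and the endocytic receptor Cubn (0.86) had the smallest p, with Slc5a2 at 0.63 without labelled-knockout library 1 and Cubn at 0.51 without wild-type library 2. None passed limma over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 0. The list stood 1.14 above the wild-type mean in labelled-knockout library 1, 0.55 in library 2 and -0.006 in library 3, and its call was lost without labelled-knockout library 1 (0.14, adjusted p = 0.19) or wild-type library 2 (0.33, adjusted p = 0.187). Podocyte markers had a median of 0.22, with 8 of 10 higher (camera adjusted p = 0.0428, adjusted p = 0.751 with an estimated correlation). Clic3 (1.08), Ptpro (0.56) and Wt1 (0.48) had higher values, Tcf21 (-1.38) lower ones, and none passed. Podocyte markers stood at 0.40, 0.36 and 0.0023 in labelled-knockout libraries 1 to 3 and 0.13, -0.077 and -0.16 in wild type. That call was lost without labelled-knockout library 1 (0.13, adjusted p = 0.146), labelled-knockout library 2 (0.17, adjusted p = 0.242) or wild-type library 3 (0.20, adjusted p = 0.175), and the median was 0.38 without labelled-knockout library 3. The podocyte call was also lost with a minimum mean of 10 (adjusted p = 0.0583). The thick limb and distal tubule markers (median 0.16 although the test's direction was lower, camera adjusted p = 0.918) and the collecting duct markers (-0.14, camera adjusted p = 0.492) were not called over all 6 libraries, with Cldn16 (-0.81), Cldn10 (-0.61), Fxyd4 (-0.67) and Atp6v1g3 (-0.73) the members of smallest p. Without labelled-knockout library 1 both were called lower (thick limb -0.40, adjusted p = 0.0431, and collecting duct -0.44, adjusted p = 0.0399), and without library 3 the collecting duct markers were called higher (0.41, adjusted p = 0.0313). Cldn10 stood at -0.39 without wild-type library 1 and Atp6v1g3 at -0.45 without labelled-knockout library 3.

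Cell cycle genes were lower in every library labelled knockout. All 28 members had lower means, with a median log2 fold change of -1.41, a 2.66-fold difference (camera adjusted p = 4.42e-18, adjusted p = 0.751 with an estimated correlation). Of these, 19 fell when adjusted over the list alone, among them Ccnb1 from 83.8 ± 19.0 to 15.9 ± 5.72 normalized counts, the anaphase activator Cdc20 from 132 ± 23.8 to 42.8 ± 12.1, Birc5 from 144 ± 31.1 to 49.4 ± 12.8 (SD, n = 3) and the topoisomerase Top2a (-1.74). The count of Ccnb1 is uncertain, since it has a near-identical copy, Ccnb1-ps. No member passed limma over all genes, 22 had an unadjusted p under 0.05, and DESeq2 called 6, all lower. The list median stood at -2.15, -0.81 and -1.01 relative to the wild-type mean in labelled-knockout libraries 1 to 3, against an SD of 0.13 between wild-type libraries. It was -0.96 without library 1.

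Fibroblast and matrix genes were lower as well, with all 15 members lower and a median of -1.51, a 2.86-fold difference (camera adjusted p = 3.31e-09, adjusted p = 0.751 with an estimated correlation). Of these, 9 fell when adjusted over the list alone, including the smooth muscle genes Acta2 (-2.43) and Tagln (-2.86), the pericyte receptor Pdgfrb (from 2351 ± 782 to 823 ± 270), the matrix protein Sparc (-1.11) and the collagen gene Col3a1 (-1.97), the last chosen after its values were seen. No member passed limma over all genes, and DESeq2 called 7, all lower. Labelled-knockout libraries 1 to 3 stood at -1.33, -0.92 and -2.58 relative to the wild-type mean. Endothelial markers had a median of -0.85, with 11 of 12 lower (camera adjusted p = 4.30e-06, adjusted p = 0.751 with an estimated correlation). Emcn (-1.08), Plvap (-1.22), Eng (-1.01) and Egfl7 (-0.92) fell when adjusted over the list alone, while no member passed limma over all genes or DESeq2. The endothelial list stood at -0.074, -0.61 and -1.58 in labelled-knockout libraries 1 to 3 and 0.15, 0.34 and -0.43 in wild type, so library 1 lay within the wild-type range. Without library 3 the endothelial median was -0.43 and Egfl7 stood at -0.61.

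**Figure D2:**
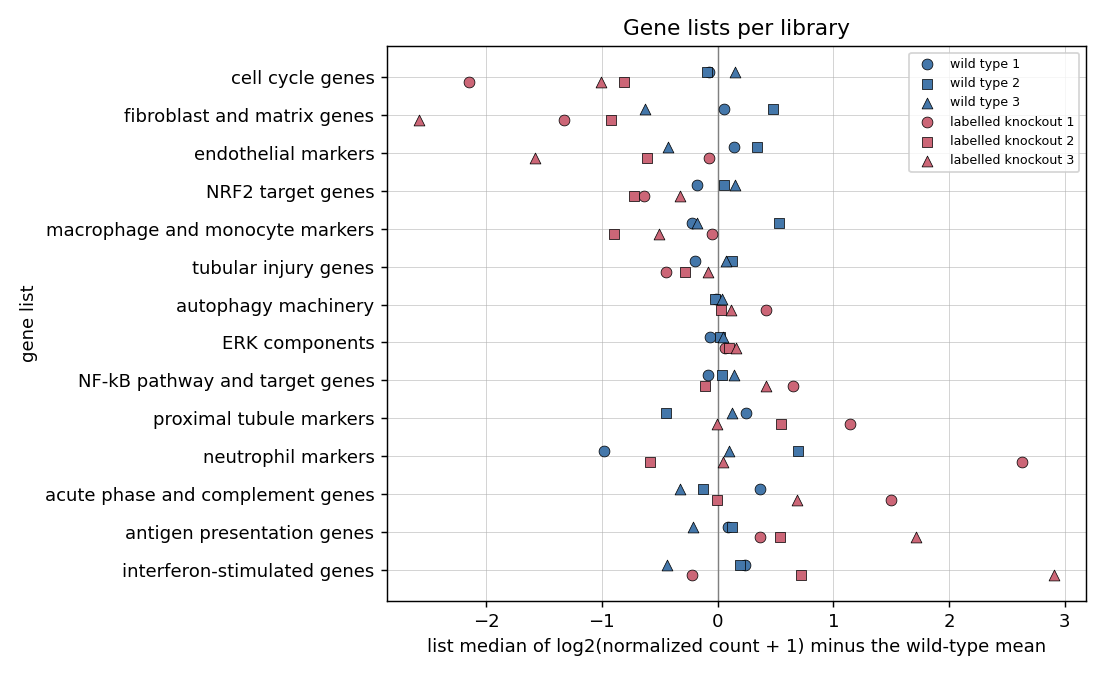
Median over each gene list of log2(normalized count + 1) minus the wild-type mean, for 14 of the 33 lists, 1 point per library, blue for wild type and red for labelled knockout. Cell cycle genes lie between -2.15 and -0.81 in labelled knockout, and interferon-stimulated genes reach 2.90 in 1 library only.

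Antigen presentation genes were higher in all 3 libraries labelled knockout, with 15 of 15 members higher and a median log2 fold change of 0.89 (camera adjusted p = 3.25e-07, adjusted p = 0.751 with an estimated correlation). The MHC class II invariant chain Cd74 rose from 1469 ± 44.4 to 2159 ± 76.1 and the class II gene H2-Ab1 from 560 ± 132 to 1113 ± 331, adjusted over the list alone. The class I transactivator Nlrc5 (2.28) and H2-DMa (1.26) had the next smallest p, no member passed limma over all genes, 6 had an unadjusted p under 0.05, and DESeq2 called 1. Labelled-knockout libraries 1 to 3 stood at 0.37, 0.54 and 1.71 relative to the wild-type mean, and without library 3 the median was 0.47, with Nlrc5 at 1.39 and H2-DMa at 0.77. Interferon-stimulated genes had a median of 1.11, with 19 of 21 higher (camera adjusted p = 3.87e-06, adjusted p = 0.751 with an estimated correlation). The T cell chemokine Cxcl9 rose, adjusted over the list alone, from 4.04 ± 0.854 to 37.0 ± 26.1, Ifih1 (0.91), Mx2 (1.90) and Zbp1 (2.15) had the next smallest p, no member passed limma over all genes, and DESeq2 called 3 members. The list stood at -0.22, 0.72 and 2.90 in labelled-knockout libraries 1 to 3, and its median was 0.30 without library 3 and 1.89 without library 1. Without library 3 Ifih1 stood at 0.53, Mx2 at 0.90 and Zbp1 at 1.18.

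Acute phase and complement genes were higher as a list (median 0.74, 14 of 18 higher, camera adjusted p = 0.000196, adjusted p = 0.751 with an estimated correlation). Complement C4b stood at 143 ± 127 and 1933 ± 1941 normalized counts and C3 at 1831 ± 1036 and 14920 ± 12712, with Lrg1 (1.45, and 0.96 without wild-type library 2) and Stat3 (0.61, and 0.40 without labelled-knockout library 1) next. None passed limma over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 1. The list stood at 1.50, -0.0086 and 0.69 in labelled-knockout libraries 1 to 3 and 0.37, -0.13 and -0.32 in wild type. The call was lost without labelled-knockout library 1 (0.33, adjusted p = 0.19), and the median was 1.37 without labelled-knockout library 2. Macrophage and monocyte markers had a median of -0.50 with 14 of 19 lower (camera adjusted p = 0.0141, adjusted p = 0.751 with an estimated correlation). The mannose receptor Mrc1 fell, adjusted over the list alone, from 148 ± 31.9 to 49.2 ± 24.1, Ms4a7 (-1.23) and C1qa (-0.71) had lower values, and the monocyte gene Ly6c2 had higher ones (1.63, and 1.04 without labelled-knockout library 3). No member passed limma over all genes, 6 had an unadjusted p under 0.05, and DESeq2 called 1. Macrophage and monocyte markers stood at -0.052, -0.90 and -0.50 in labelled-knockout libraries 1 to 3 and -0.22, 0.53 and -0.17 in wild type. The call was lost without wild-type library 2 (-0.28, adjusted p = 0.275) or labelled-knockout library 2 (-0.37, adjusted p = 0.287), and the median was -0.81 without labelled-knockout library 1.

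Neutrophil markers followed single libraries more than the groups. They stood at -0.98, 0.69 and 0.10 relative to the wild-type mean in wild-type libraries 1 to 3 and at 2.63, -0.59 and 0.049 in labelled-knockout libraries 1 to 3. The median was 0.69 with 17 of 23 higher (camera adjusted p = 0.0428, adjusted p = 0.891 with an estimated correlation), and -0.46 without labelled-knockout library 1. The call was also lost without wild-type library 1 (0.46, adjusted p = 0.795) or wild-type library 3 (0.68, adjusted p = 0.0678), and the median was 1.42 without labelled-knockout library 2. The neutrophil call was lost with a pseudocount of 0.1 (adjusted p = 0.065) and with a minimum mean of 10 (0.36, adjusted p = 0.243) as well. The granule genes Ngp (3.74), Camp (1.96), Mpo (1.32) and the protease gene Asprv1 (1.06) had the smallest p, and none of the 23 had an unadjusted p under 0.05. Without labelled-knockout library 1 the log2 fold changes of all 4 were smaller but still positive. Ngp stood at 1.77, Asprv1 at 0.39, and Camp at 0.70 and Mpo at 0.67, both with a mean below the minimum for testing. The wild-type means of Ngp, Camp and Mpo were only 0.93, 0.31 and 0.31 normalized counts. Asprv1 stood at 0.51 without wild-type library 1, Camp at 3.10 without labelled-knockout library 2 and Mpo at 2.14 without library 3. The CXCR2 ligands had a median of 0.32 (camera adjusted p = 0.345), with Cxcl1 at 623 ± 232 and 1378 ± 1032 normalized counts and Mif at 0.18. The log2 fold change of Cxcl1 was 0.97, with 0.39 without labelled-knockout library 1 and 0.62 without wild-type library 2, and that of Mif was 0.0088 without wild-type library 2 and 0.27 without wild-type library 1. T and NK cell markers (median 0.58, camera adjusted p = 0.203, with Gzmb at 2.32 and Cd8b1 at 2.08), B and plasma cell markers (-0.077, camera adjusted p = 0.768, with Jchain at -1.77 and Igha at -2.69) and erythrocyte genes (0.59, camera adjusted p = 0.527, with Alas2 at 1.47) were not called. The median of the T and NK cell markers ran from 0.21 to 0.71 over the leave-outs and was 1.18 with a minimum mean of 10, never with a call. Without labelled-knockout library 1 Alas2 stood at 0.039 and Igha at -1.31, while Alas2 stood at 0.93 without wild-type library 2 and 2.41 without labelled-knockout library 3.

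NRF2 target genes, which encode antioxidant and detoxifying enzymes, were lower as a list (median -0.55, 11 of 14 lower, camera adjusted p = 0.00972, adjusted p = 0.751 with an estimated correlation). The glutathione transferases Gsta2 (from 7523 ± 2424 to 3393 ± 983) and Gsta4 (from 1112 ± 198 to 485 ± 202) fell and Gclc, the rate-limiting enzyme of glutathione synthesis, rose (from 5767 ± 456 to 8444 ± 1062), adjusted over the list alone. Cbr3 was next by p (-2.14, and -1.25 without labelled-knockout library 1), no member passed limma over all genes, and DESeq2 called 2, both lower. The list stood at -0.63, -0.73 and -0.33 in labelled-knockout libraries 1 to 3 and -0.18, 0.059 and 0.15 in wild type. The call was lost without wild-type library 3 (-0.45, adjusted p = 0.0827), and the median was -0.30 without labelled-knockout library 2 and -0.31 without wild-type library 2.

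Mitochondrially encoded genes had a median of 0.35 (camera adjusted p = 0.122), and of 0.21 without labelled-knockout library 1. When adjusted over the list alone, mt-Nd3 fell and mt-Atp6 rose (from 2450 ± 1446 to 6832 ± 2536), and the 12 genes other than mt-Nd3 had a median of 0.36. Lysosome genes (median 0.15, camera adjusted p = 0.0673, with Scarb2 at -0.55 and Ctsa at 0.53), heat shock genes (0.26, camera adjusted p = 0.216, with Bag3 at 0.62 and Hspe1 at -0.48) and unfolded protein response genes (0.11, camera adjusted p = 0.456, with Xbp1 at 0.56 and Manf at -0.28) were not called, although lysosome genes were called higher without wild-type library 3 (0.17, adjusted p = 0.0244) or labelled-knockout library 2 (0.23, adjusted p = 0.00592). Nor were glycolysis and hypoxia genes (0.027, camera adjusted p = 0.345, with Ndrg1 at 1.16 and Gapdh at -1.92) or fatty acid oxidation genes (-0.039, camera adjusted p = 0.873, with Acaa1b at -0.83 and Etfb at -0.43), although glycolysis and hypoxia genes were called higher without labelled-knockout library 3 (0.22, adjusted p = 0.0396). Nuclear-encoded oxidative phosphorylation genes had a median of 0.023 against a mean of -0.056 and a test direction of lower (camera adjusted p = 0.569, with Ndufa2 at -0.48 and Uqcrb at -0.72), and were called lower without labelled-knockout library 1 (median -0.13, adjusted p = 0.00623). Among cell death lists, apoptosis genes (0.045, camera adjusted p = 0.918, with Cycs at -0.58 and Bad at -0.56), ferroptosis genes (0.18, camera adjusted p = 0.809, with Ptgs2 at -0.96 and Alox15 at 1.75) and pyroptosis and necroptosis genes (-0.064 against a mean of 0.082 and a test direction of lower, camera adjusted p = 0.918, with Ripk3 at -0.89 and Zbp1) were not called either. Of the genes named here, Alox15 stood at 0.57, Bag3 at 0.41, Bad at -0.33 and Manf at -0.11 without labelled-knockout library 1, and Alox15 at 2.91 and Gapdh at -1.14 without library 3. Hspe1 stood at -0.24, Uqcrb at -0.48 and Manf at -0.10 without wild-type library 1, and Acaa1b at -0.54 without wild-type library 3. The median of the heat shock genes was 0.055 without labelled-knockout library 1. Sex-linked genes (median 0.0047, test direction lower, camera adjusted p = 0.918, with Eif2s3y at -0.52 and Xist at 1.55) had Ddx3y, a Y-linked gene chosen after its values were seen, at 589 to 1510 normalized counts and Xist at 7.80 or less in all 6 libraries. Eif2s3y stood at -0.78 without labelled-knockout library 1 and -0.32 without library 3.

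The camera test called 14 of 33 lists, 8 higher and 6 lower, and 0 with an estimated correlation or with fry's test of movement in 1 direction (smallest fry adjusted p = 0.536). The mixed test of fry, for change in either direction, called 2 lists, mitochondrially encoded genes (fry adjusted p = 0.00025) and podocyte markers (fry adjusted p = 0.0477). The mitochondrially encoded list includes mt-Nd3, whose count is uncertain. The count of its member mt-Nd4l is uncertain too, since it shares 294 identical bases with the nuclear pseudogene Gm10222, chosen after its values were seen. The list was not tested without these members. The 9 other splits of the 6 libraries into 3 and 3 gave 10 to 15 lists each, so the number of lists called does not set the genotype split apart.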

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

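The minimum mean of 10 and the TMM scaling of the limma values were chosen only after the data were seen. The edgeR test with TMM factors was fixed beforehand for raw counts, but its use as an alternative on recovered reads was chosen afterwards. All other alternatives were fixed before the data were examined. That whole reads could be recovered for DESeq2 and for edgeR with RLE factors was learned only from the deposited values. Gm8730 was past the threshold in 15 of 15 settings (log2 fold change 3.70 to 3.96, largest adjusted p = 0.0173 over limma, edgeR and DESeq2). The number of genes called with limma was 5 without the filter on low values (3 higher, 2 lower) and 4 with TMM scaling (3 higher, 1 lower). DESeq2 called 316 (105 higher, 211 lower), of which 1 was called by limma, and the cause of the gap was not tested. Leaving out 1 library gave 1 to 6 genes, 1 to 3 higher and 0 to 3 lower, with 6 without labelled-knockout library 1 and 3 without library 3. With the replicate number as a block (replicate block) limma called 16 genes, 6 higher and 10 lower, and lists called went from 14 to 13, podocyte markers being lost (median 0.22, adjusted p = 0.0817). The labels do not say that the numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.046, -0.14 and 0.13 across 15915 genes, and not every library correlated best with its own number. With so few libraries in each group these correlations cannot exclude a pairing. Lists called were 0 with an estimated correlation and 0 with fry, where correlated members count for less or lists are not set against other genes, and 11 to 15 in the other settings.

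The Cxcr2 log2 fold change ran from -0.27 to 0.94 over the leave-outs, the lowest without wild-type library 1, and rests on 19 to 96 reads per library. The value of Mapk3 ran from -0.045 to 0.19 and that of Havcr1 from -2.29 to 0.39, positive only without labelled-knockout library 1. Besides Cxcr2, these 2 were the only ones of 109 other named genes whose sign turned. Leaving out 1 library turned or moved the log2 fold change of 41 of the 109 by over 1.5 times, 23 of them without labelled-knockout library 1 and 15 without library 3. Across tools and other settings, values that moved by over 1.5 times were Cxcr2 (0.24 to 0.25) and Havcr1 (-0.056 to -0.052) with DESeq2 and edgeR, and Alas2 with edgeR (2.73 to 2.74). DESeq2 also moved Ngp (6.88), Camp (4.85), Mpo (3.21), Alox15 (3.74) and Alas2 (2.74), all without an adjusted p there. A pseudocount of 0.1 moved Ngp (5.89), Camp (3.23), Mpo (2.54), Gzmb (4.46), Cd8b1 (4.19), Alox15 (2.89) and Xist (2.85). The camera direction of 14 of the 33 lists turned in at least 1 setting. The median alone changed sign over the leave-outs for ERK components (-0.030 to 0.13) and unfolded protein response genes (-0.022 to 0.13). The medians of the 14 over the leave-outs ran from -0.40 to 0.63 for thick limb and distal tubule markers (0.16 with the replicate block), -0.50 to 0.41 for collecting duct markers, -0.46 to 1.42 for neutrophil markers, -0.41 to 0.41 for B and plasma cell markers, -0.59 to 1.19 for erythrocyte genes and -0.31 to 0.80 for CXCR2 ligands. They ran from -0.38 to 0.11 for ERK response genes, -0.28 to 0.063 for pyroptosis and necroptosis genes, -0.061 to 0.13 for apoptosis genes (0.045 with fry), -0.033 to 0.29 for ferroptosis genes and -0.16 to 0.11 for fatty acid oxidation genes (-0.039 with the replicate block). They ran from -0.13 to 0.11 for nuclear-encoded oxidative phosphorylation genes, -0.16 to 0.22 for glycolysis and hypoxia genes and -0.10 to 0.19 for sex-linked genes (0.0047 with fry). Of the 14 lists called, 5 passed in all 6 leave-outs: cell cycle, fibroblast and matrix, endothelial, antigen presentation and interferon-stimulated genes. Labelled-knockout library 1 ended 7 of the other calls when left out. A pseudocount of 0.1 ended the tubular injury and neutrophil calls, and a minimum mean of 10 those and the podocyte call. Lists called only with a library left out were ERK response, thick limb and distal tubule, collecting duct, nuclear-encoded oxidative phosphorylation, lysosome, and glycolysis and hypoxia genes.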

Other observations

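The tests of Cxcr2 against neutrophil markers, of linked DNA, of fat cell markers, of dilution and of copies with related genes taken once were chosen only after the results were seen, while the tests of exchanged libraries, near-identical copies and other splits were set down before. The genes named in this paragraph and the next were chosen after their values were seen. Labelled-knockout library 1 held transcripts of brown and white fat: Cidea at 2626 normalized counts, the adipokine Adipoq at 2174, Cfd at 19042 and Fabp4 at 20756. Wild-type library 1 and labelled-knockout library 2 held smaller amounts, with Cfd at 727 and 872, and the other 3 libraries had Cfd at 0. The same library had the acute phase gene Saa3 at 7510 against 277 or less elsewhere, and the immediate early gene Fosb at 1446 against 29.6 or less.

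Labelled-knockout library 3 held high levels of the GTPase genes Iigp1 (10492 normalized counts against 726 or less in the other 5 libraries), Igtp (12575 against 1121 or less) and Gbp2 (5808 against 571 or less). The class II transactivator Ciita stood at 2519 there against 249 or less, and the chemokine gene Cxcl10 at 4547 against 425 or less. The fibrinogen gene Fga, which injured tubules express, stood at 36777 against 7639 or less. Among kallikreins, all 15 Klk1b genes had lower means in the libraries labelled knockout and 13 had no overlap between the groups. These genes lie close together and are similar in sequence, so they are not independent of one another.

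The genotype split gave 1 gene past the threshold and the other splits at most 0, and it gave 14 lists where the other splits gave at most 15 (6 of the 10 splits reached 14). The 10 splits are too few for a share under 0.05.

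Cxcr2 reads in the libraries labelled knockout had a mean of 63.8 normalized counts against 53.9 in wild type. The labelled split separated 148 genes by at least 4-fold without overlap and no other split more than 103. That was the outcome set down beforehand for no exchange of 1 or 2 libraries between the groups. But the 10 splits are too few for a share under 0.05, so such an exchange is not excluded. An exchange of all 3 for all 3 would give the same split and stays open too. Cxcr2 could follow the neutrophil content of each kidney: over the 6 libraries it correlated with the mean of the neutrophil markers (Pearson's r = 0.794, permutation p = 0.0667; Spearman's rho = 0.886, permutation p = 0.0333; 1 relation tested), and r was 0.793 to 0.888 without any single library. Without labelled-knockout libraries 1 and 2, the farthest from the median marker level, r was 0.992, but over 4 libraries only, so it adds no support, and the relation remains a hypothesis. Reads from parts of the gene outside a deletion, and a deletion in some cell types only, were not testable from whole-gene counts.

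Genes that split the groups cleanly include several with near-identical copies. A candidate explanation, which stays open, is a difference in strain background between the groups, where sequence variants move reads between copies: 12 of the 20 genes with the smallest p had such a copy (60%), against 32.5% of 400 random genes (Fisher's exact test, one-sided p = 0.0127), but some are copies or neighbours of one another, and with such genes taken once the count was 9 of 17 (52.9%, one-sided p = 0.0713). The nuclear copy Gm28438 on chromosome 1 (24612775 to 24613119) differs from mt-Nd3 over 345 aligned bases only by T3C, counted from 1 at the 5′ end of mt-Nd3, and the means (labelled knockout minus wild type, normalized counts) differed by -497 for mt-Nd3 and 965 for Gm28438, and by 1349 for Gm8730 and -5159 for Rplp0, which share 98.7% of 954 bases. Within each pair the gain and the loss were unequal in size, and the fall of Rplp0 did not pass (limma adjusted p = 0.549). These means therefore do not show that reads moved between copies. Of the 20 genes, 1, Wdfy1, lies within 20 Mb of Cxcr2, so linked variants that change genes in that window account for 1 of them at most. The count cannot decide on linked DNA that acts on genes elsewhere, which stays open. Strain cannot be separated from genotype because the labels name no strain.

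Labelled-knockout library 1 stands apart in fat, blood and cell cycle genes. Fat tissue in that sample may account for part of this, as 15 of 20 fat cell markers were at least 4-fold above every other library, although 8 of the 20, such as Cebpa and Prdm16, stood at 10 or more normalized counts in each of the other 5. Dilution of kidney RNA by that tissue is argued against as the only cause of its lower cell cycle genes (-1.86 against the other 5 libraries) and injury genes (-0.44), because proximal tubule markers were higher there (1.08, 19 of 25). A part of dilution in these differences stays open. A milder or earlier injury in that kidney was not tested, and no label bears on it.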
